A study of Drosophila melanogaster with 8 samples.

How the data were processed

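Single-cell RNA-seq was run on Kenyon cells, the intrinsic neurons of the mushroom body, from brains of adult female Drosophila melanogaster. Per the labels' protocols, the flies carried GFP in the OK107 pattern and a tdTomato reporter under split-GAL4 drivers for Kenyon cell subtypes, optic lobes were removed, brains were dissociated with collagenase and dispase in the presence of actinomycin D, and DRAQ5-positive, GFP-positive cells were sorted. The tdTomato signal was not used in the sort, per the labels. Each of the 8 libraries is a pool of at least 8 brains, per the labels, so a library is the replicate here. P-values of genes and of shares measure the spread between libraries. With 2 libraries, those of α/β-like cells in pool C rest largely on the spread that edgeR shares between genes. Camera p-values compare the genes of a list with all other genes and depend on the correlation assumed between genes. Those of Fisher's exact tests count cells. Pool A (1 library, replicate 1) combined drivers for γm with γd, for α′/β′m and for α/βp. Pool B (5 libraries, replicates 2 to 6) combined drivers for γd, α′/β′ap and α/βs. Pool C (2 libraries, replicates 7 and 8) combined drivers for γm with γd, for α′/β′m and for α/βc. Pools A and C share the γ and the α′/β′ driver and form driver set 1 (3 libraries), and pool B is driver set 2 (5 libraries).

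The deposited matrices hold UMI counts per gene and barcode that the authors made with Cell Ranger 7.0.0 on the BDGP6 genome, per the labels' protocols. The annotation version behind those counts is not given in the sources used here. A BDGP6 annotation used here for coordinates contained 17751 of the 17830 gene IDs (99.6%). The genome sequence was not used here. The files hold 40397 barcodes and 23892 features, of which features that are not genes took 0.234% of UMIs and were left out apart from the transgenes EGFP and tdTomato. Replicates 2 and 3 shared 44 barcodes (3.15% of the smaller library), and every other pair at most 0.254% of its barcodes. Of the 44, 43 had over 10 times more UMIs in replicate 2 (median 46050) than in replicate 3 (median 608), as when molecules of one library are read in another. These 43 were kept among the analysed cells of replicate 3. Of the 44 barcodes, 0 were Kenyon cells and 0 held a roX1 UMI in either library. Without the 43 the Kenyon cell share of replicate 3 was 31.4%.

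The following choices were made before the data were examined unless the text says otherwise. Cells with at least 300 genes, at least 500 UMIs and at most 15% mitochondrial UMIs were kept, and scrublet in scanpy 1.11.5 with default settings was run per library to remove doublets. The filters removed 1786 barcodes and scrublet removed 332 of the 38611 cells that passed (0.860%), which left 38279. In replicate 1 scrublet marked 3 cells (0.0467%), so the caller did not work there, and an alternative that also removed the 5% of cells with the highest doublet scores was added after the data were seen. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were chosen with the library as batch, values were scaled within libraries, and cells were clustered with 30 principal components, 15 neighbours and the Leiden method at resolution 1 (leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0, numpy 2.4.6, Python 3.11.15). Transgenes, mitochondrial genes and ribosomal protein genes were kept out of the variable genes.

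Clusters were called γ-like, α′/β′-like or α/β-like from fixed markers. The markers were ey, mub, Dop1R2, Dop1R1, Mef2, dac, rut and Pka-C1 for all Kenyon cells, ab, trio, Imp, chinmo, 5-HT1B and sNPF for γ, mamo, trio, CG32204 and Galphai for α′/β′, and Fas2, sNPF, Hr39 and 5-HT1A for α/β. A cluster needed at least 100 cells, 7 Kenyon cell markers and 3 class markers at least 2-fold above the median cluster after adding 10 CPM, a scoring set after the data were seen. Its 10 genes furthest above the median cluster also had to hold at least 1 of these markers. No fixed marker list of another cell type could have more members among those 10 genes. Clusters with at least 3 fixed glial markers above the median cluster by 2 or more on the log2 scale were called glia-like. These markers did not have to be the leading genes of the cluster. All other cells are called other cells. Sub-clusters within a class used Leiden resolution 0.5 and kept a number, since the reporter alone gives a subtype. For tests between classes, genes were divided into 2 sets (8903 and 8927 genes) by the last digit of their ID. Cells were clustered on 1 set and the genes of the other set were tested on those classes, so no tested gene took part in that clustering. The naming of the clusters drew on both sets. Markers of other cell types, such as DAT, had a part in the naming rule and were also tested.

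Raw UMI counts were summed per library and class, giving 24 sums of at least 20 cells. Tests used edgeR 4.0.16 (limma 3.58.1, R 4.3.3) with TMM factors, filterByExpr and the quasi-likelihood F test, with Benjamini-Hochberg adjustment at 0.05. Every adjusted p-value of a gene below is from edgeR's quasi-likelihood test with that adjustment. Class contrasts used all 8 libraries with the library as a block and left out the class markers. Reporter contrasts compared cells with at least 1 tdTomato UMI with cells without one, in sums of at least 3 positive cells, with the library as a block, within pool B and within pools A and C, and for α/β-like cells within pool C alone because pools A and C differ in that driver. Their difference between driver sets was tested as an interaction. The driver sets were also compared within each class over all 8 libraries, with no block. Contrasts between sub-clusters had been planned only for a matrix without the reporter and were not run. Shares of cells were compared with 2-sided exact permutation tests in scipy 1.17.1. The smallest p-value these can give for 3 against 5 libraries is 0.0357. Groups share no replicate numbers.

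Genes were named by a fixed rule. For a class contrast these are the 10 largest log2 fold changes in each direction among genes past the threshold with a mean of at least 50 CPM and the same direction in all 8 libraries, and from each list the 2 members with the smallest adjusted p-value above the same CPM floor. For reporter contrasts the rule takes the 5 largest in each direction, with the same direction in every library tested. For their interactions it also takes 5, with the same direction of the reporter effect in the libraries of set 2 only. For the driver sets it takes 5 in each direction without the rule on libraries. The transgenes, roX1 and roX2 are always given.

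The lists fixed at the start cover neuropeptides, neuropeptide receptors, monoamine receptors, acetylcholine receptors, receptors of GABA, glutamate and histamine, transmitter synthesis and transport, voltage-gated and potassium channels, cAMP signalling and olfactory memory, nitric oxide and cyclic GMP, Dpr and DIP surface proteins, Beat and Side surface proteins, axon guidance and adhesion, transcription factors of neuronal identity, synaptic vesicle release, innexins, heat shock, activity-regulated genes, cytosolic ribosomal proteins, mitochondrially encoded genes and the dosage compensation RNAs. Gpa2 and unc-10 matched no symbol in the files. Lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation.

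On simulated counts with a dispersion of 0.02, the γ-like against α/β-like test recovered 86.6% of genes changed 1.5-fold, 98.5% of those changed 2-fold and all of those changed 4-fold, with 3.08% of calls false. The share of 2-fold changes recovered was 71.4% for the γ reporter contrast in pool B, 16.4% in pools A and C, 19.7% for α′/β′ in pool B, 67.2% in pools A and C, 54.9% for α/β in pool B and 37.3% in pool C, where 7.37% of calls were false. For the interactions it was 13.0% in γ-like, 27.1% in α′/β′-like and 19.2% in α/β-like cells, and for the driver sets 89.4%, 85.1% and 88.1% in the same order. Other shares of false calls above 5% were 7.84% for the α/β interaction and 7.50% and 6.67% for the driver sets in γ-like and α′/β′-like cells. All simulated sums had the same profile apart from their size and the changed genes, with no other differences between libraries. Only genes above a count floor were changed. The real libraries also differ from each other, so the real shares can be lower, above all for the driver sets, tested with no block.

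Alternatives were DESeq2 1.42.0 with its size factors, RLE factors, no filter on low counts, no library block, doublets kept, stricter cell filters, another clustering resolution, classes from all genes, thinned counts, a reporter threshold of 2 UMIs, pool B against pool C alone, and each library left out in turn. Added after the data were seen were the stricter doublet removal, at least 5 positive cells per sum, and a term for replicates 6, 7 and 8 in the driver set comparison. Confidence intervals of shares are exact Clopper-Pearson intervals at 95%, and they and the limits given for counts of 0 (3 counts) cover counting error only.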

Results

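Brains of adult female flies were pooled into 8 single-cell libraries, and gene expression was measured as UMI counts per cell. Pool A gave 1 library (replicate 1), pool B gave 5 (replicates 2 to 6) and pool C gave 2 (replicates 7 and 8), and the pools differ in which Kenyon cell subtypes carried the tdTomato reporter. In the order of the replicates the libraries held 45743690, 19588576, 37811673, 68908894, 67428379, 70205608, 70377903 and 67885626 UMIs. The median UMI count per barcode was 6000 in replicate 1, 11500 in replicate 2, 10029 in replicate 3, 9451 in replicate 4, 9380.5 in replicate 5, 10910.5 in replicate 6, 9974 in replicate 7 and 10157.5 in replicate 8.

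Kenyon cells made up 27.4% ± 4.91 of the analysed cells per library (mean ± SD, n = 8 libraries), from 18.1% in replicate 1 to 34.1% in replicate 2. Of the 38279 cells, 4965 were γ-like, 1614 α′/β′-like and 3442 α/β-like. The γ-like cells held the transcription factor ab at 1101 ± 67.7 CPM, against 9.86 CPM in α′/β′-like and 19.2 CPM in α/β-like cells. The α′/β′-like cells held the transcription factor mamo at 13509 CPM and the α/β-like cells the adhesion molecule Fas2 at 899 CPM. These markers set the names and are not results. Of the α′/β′ markers, Galphai was near 0 (0.356 CPM in α′/β′-like cells) and CG32204 was higher in γ-like cells (1290 CPM) than in α′/β′-like cells (375 CPM). A further 162 cells lay in clusters with the Kenyon cell markers that stayed unnamed by the scoring set after the data were seen. They made up 4.28% of Kenyon-like cells in pool A, 1.04% to 2.50% in the libraries of pool B and 0.577% and 0.822% in those of pool C. Of the γ markers, chinmo was lowest in γ-like cells (264 CPM, against 1390 and 702 CPM), and trio, a marker of γ and α′/β′, was at 474 CPM in γ-like and 1533 CPM in α′/β′-like cells. In all, 997 cells were glia-like, some of them among the unnamed, and the remaining sorted cells were not typed further.

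The shares of the classes were compared between driver sets, since the sort took all GFP-positive cells and the pools were built from the same classes. The γ-like share of analysed cells was 13.5% ± 2.53, the α′/β′-like share 4.44% ± 1.10 and the α/β-like share 9.41% ± 1.69 (SD, n = 8 libraries). Set 2 lay above set 1 by 1.74 percentage points for γ-like (exact permutation p = 0.5), 0.348 for α′/β′-like (exact p = 0.75) and 0.279 for α/β-like cells (exact p = 0.821). These differences were smaller than the spread between libraries. Without replicate 1 the 3 differences became −0.381, −0.604 and −0.551. Without replicate 2 the α′/β′-like one became −0.0218 and the α/β-like one −0.119. Without replicate 3 the α/β-like one became −0.376.

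The first question is which genes separate the main Kenyon cell types, starting with γ-like against α/β-like cells. Of 6251 genes tested, 3591 differed, 597 of them by more than 2-fold. Of these, 1829 were higher in γ-like cells and 1762 in α/β-like cells. Pka-C3, a catalytic subunit of the protein kinase A family, was 335-fold higher in γ-like cells, at 488 ± 30.6 CPM against 1.47 ± 1.88 CPM (mean ± SD, n = 8 libraries). Its log2 fold change was 8.39 ± 0.12 (SE, adjusted p = 5.58e-36), and the gene (FBgn0000489) lies on 3L at 15925805 to 15954797. The glutathione S-transferase GstD11 (log2 fold change 7.59 ± 0.11, 579 CPM against 3.24 CPM), the carbonic anhydrase CAH2 (7.07 ± 0.14) and the RNA-binding protein Rbp6 of the Musashi family (6.09 ± 0.17) followed. The zinc finger homeodomain factor zfh2 was higher by 5.37 ± 0.09, the glypican dlp by 4.73 ± 0.10, and CG43658, tbc, mtt and cmpy by 4.99 to 5.62. In α/β-like cells, the Fat-like cadherin kug (−8.55 ± 0.14), the immunoglobulin surface protein DIP-kappa (−8.14 ± 0.13, 3.21 CPM in γ-like against 770 ± 52.3 CPM), the apical polarity protein crb (−8.14 ± 0.13, 2.76 against 678 ± 132 CPM) were among the genes with the largest differences. So were the glycoprotein-hormone-type receptor Lgr1 (−7.68 ± 0.20) and the diuretic hormone receptor Dh44-R2 (−6.12 ± 0.12). The PDGF- and VEGF-like ligand Pvf3 (−5.84 ± 0.14), the surface protein beat-VII (−5.68 ± 0.08), CG43759, SP1173 and Lmpt completed the 10 named on that side. Each of these 20 genes had the same direction in 8 of 8 libraries.

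Gene families also differed between γ-like and α/β-like cells. Genes for transmitter synthesis and transport were higher in γ-like cells for 8 of 10 tested members and lower for none (camera adjusted p = 0.000202, and 0.0124 with an estimated correlation). They were led by Ddc, which makes dopamine and serotonin (2.43 ± 0.05), and the amino acid transporter Eaat2 (1.12 ± 0.05). Of 10 acetylcholine receptor genes, 7 were higher, among them nAChRalpha7 (3.46 ± 0.06) and nAChRalpha6 (1.39 ± 0.03), and 2 lower (camera adjusted p = 0.00177, not passing at 0.0520 with an estimated correlation). Of 31 transcription factors, 17 were lower and 8 higher (camera adjusted p = 0.00802, not passing at 0.182 with an estimated correlation). Lower were the steroid-response factor Eip93F (−2.66 ± 0.03, 552 CPM against 3494 CPM) and the zinc finger factor dati (−3.04 ± 0.05). Ribosomal protein genes were higher for 75 of 83 members, with RpS15 at 0.74 ± 0.03 and RpS9 at 0.84 ± 0.03, and 3 were lower (camera adjusted p = 1.14e-25, not passing at 0.0758 with an estimated correlation). Mitochondrially encoded genes were higher for 15 of 15 (4.31e-09, not passing at 0.0793 with an estimated correlation), with mt:lrRNA at 1.26 ± 0.03 and mt:ND1 at 1.16 ± 0.04.

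Other lists held genes on both sides between γ-like and α/β-like cells, with camera adjusted p from 0.0731 to 0.994. Of 10 monoamine receptors 6 were higher in γ-like cells and 3 lower, among them the octopamine receptors Octbeta3R (−5.17 ± 0.08) and Oamb (−1.39 ± 0.04). Of 15 neuropeptide receptors 8 were higher and 7 lower. Of 15 GABA, glutamate and histamine receptors 4 were higher, with mGluR at 2.96 ± 0.05, and 9 lower, with the glutamate-gated chloride channel GluClalpha at −1.68 ± 0.04. In intracellular signalling, 19 of 35 cAMP and memory genes were higher and 10 lower (the phosphodiesterase Pde8 at −2.13 ± 0.04). For cyclic GMP, 2 of 6 nitric oxide and cyclic GMP genes were higher (Pde1c 1.14 ± 0.03) and 3 lower (Pde6 −2.55 ± 0.07). Of 34 channel genes 10 were higher, with the cyclic-nucleotide-gated channel Cngl at 1.98 ± 0.04 and the calcium channel subunit Ca-Ma2d at 2.17 ± 0.05, and 17 lower. On the cell surface, 11 of 19 Dpr and DIP genes were higher and 7 lower (dpr6 −1.96 ± 0.05). Of 16 Beat and Side genes 6 were higher and 5 lower (beat-IIIb −1.17 ± 0.05). With doublets kept camera put that list higher (median 1.83, adjusted p = 0.00808), against a median of 0.02 here (adjusted p = 0.933). Of 45 guidance and adhesion genes 17 were higher and 15 lower (kirre −3.58 ± 0.07, trn −3.14 ± 0.07). Of 30 genes for vesicle release 14 were higher (sff 0.90 ± 0.04) and 8 lower (the active zone protein brp −0.55 ± 0.03). Of 6 neuropeptides 2 were higher and 4 lower (spab −0.95 ± 0.12). Of 7 heat shock genes 1 was higher and 3 lower (Hsromega −0.55 ± 0.03, stv −0.61 ± 0.05). Of 10 activity-regulated genes 6 were higher (CG46385 1.99 ± 0.05, the nuclear receptor Hr38 1.15 ± 0.05) and 2 lower. The gap junction gene shakB, the innexin that passed the filter, was higher by 0.23 ± 0.03. Adjusted over the list alone, the counts of genes past the threshold were 28 in place of 27 channels, 19 in place of 18 Dpr and DIP genes, 26 in place of 25 transcription factors and 9 in place of 8 activity-regulated genes, with the other lists as above. The median log2 fold change was 0.30 and the mean −1.26 for the neuropeptide receptors, and 0.39 and −0.13 for the Dpr and DIP genes.

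**Figure D1:**
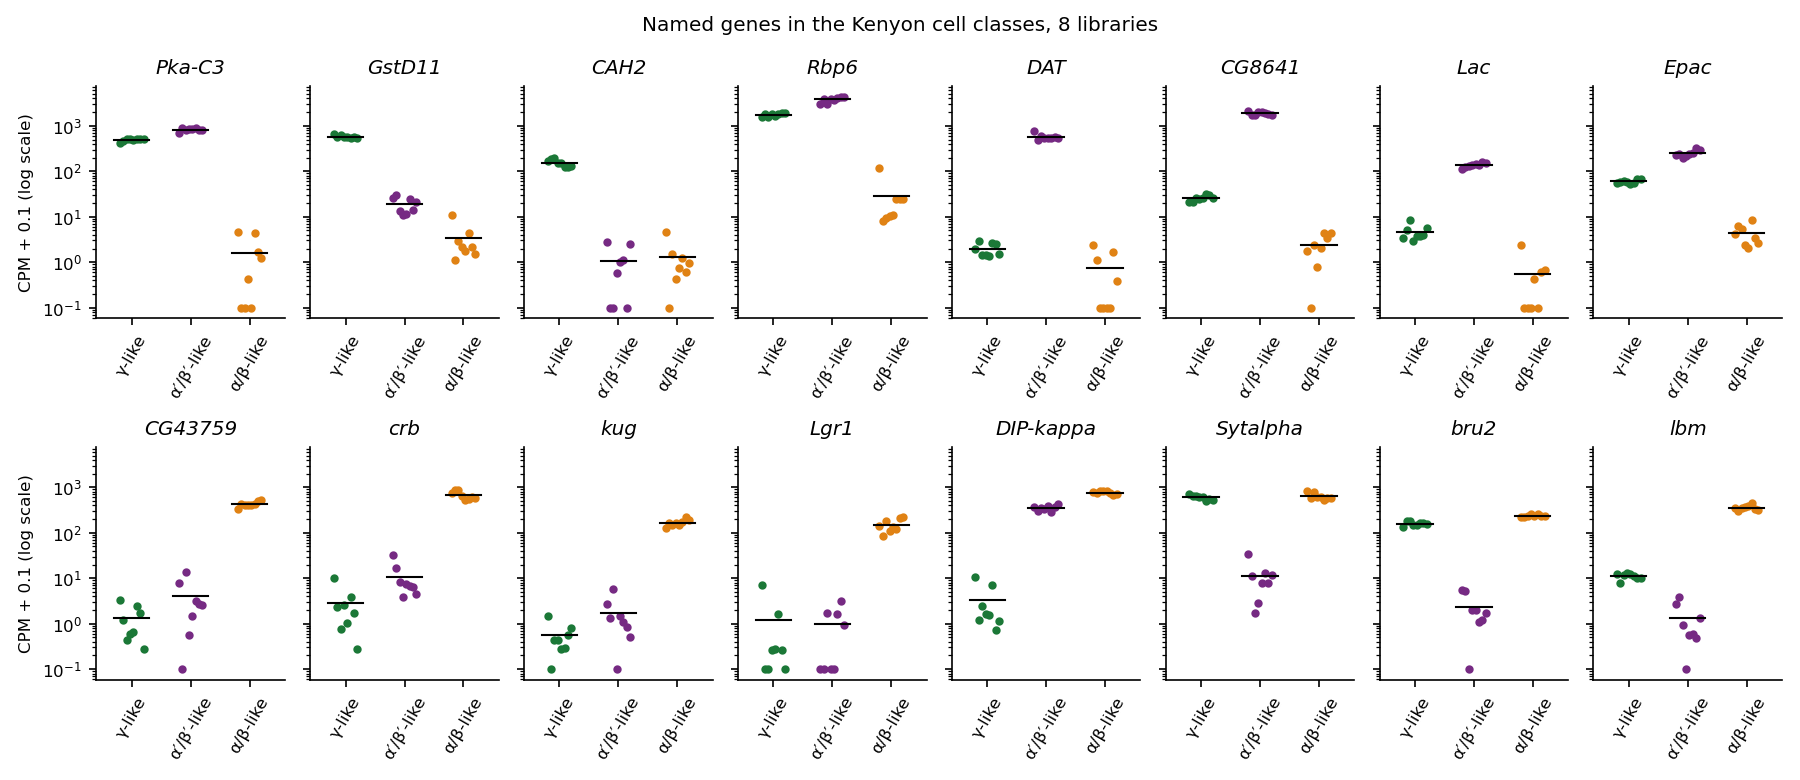
Expression of named genes in γ-like, α′/β′-like and α/β-like cells, in CPM plus 0.1 on a log axis, with 1 point per library (n = 8) and a line at the mean. Pka-C3 lay at a mean of 488 CPM in γ-like and 1.47 CPM in α/β-like cells.

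α′/β′-like cells differed from α/β-like cells in 3855 of 6251 genes, 1947 higher and 1908 lower, 841 of them by more than 2-fold. DAT, the dopamine transporter, was 919-fold higher in α′/β′-like cells, at 569 ± 82.5 CPM against 0.641 ± 0.881 CPM (n = 8 libraries). Its log2 fold change was 9.84 ± 0.12 (SE, adjusted p = 2.86e-38), and the gene (FBgn0034136) lies on 2R at 16558567 to 16565238. DAT is also a marker of monoaminergic neurons, but the vesicular transporter Vmat (1.36 CPM) and the dopamine synthesis gene ple (0.694 CPM) were near 0 in α′/β′-like cells. CG8641 (9.47 ± 0.08, 1890 ± 157 CPM against 2.31 CPM), Pka-C3 (9.15 ± 0.11), and the gustatory receptor family gene Gr77a (8.75 ± 0.21) were higher as well. So were the immunoglobulin protein Lac (8.22 ± 0.19) and the cAMP-activated exchange factor Epac (6.04 ± 0.11), with Rbp6, CG1674, CG3655 and cmpy. The tetraspanins lbm (−8.67 ± 0.12) and Tsp42En (−7.68 ± 0.13), the RNA-binding protein bru2 (−7.05 ± 0.13) and the synaptotagmin Sytalpha (−6.02 ± 0.11, 11.2 CPM against 641 CPM) were lower. Lmpt, Lgr1, CG43759, kug, crb and CG33090 were lower by −7.37 to −5.87. All of these directions held in 8 of 8 libraries.

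Among the families, neuropeptide receptors were lower in α′/β′-like than in α/β-like cells for 11 of 15 members and higher for 1, led by Lgr1 (−7.19 ± 0.25) and Dh44-R2 (−4.91 ± 0.13) (camera adjusted p = 0.000756, and 0.0379 with an estimated correlation). Transmitter genes were higher for 9 of 10 members and lower for 1, with the acetylcholinesterase gene Ace at 3.24 ± 0.05 beside DAT (camera adjusted p = 0.000574, and 0.0403 with an estimated correlation). Transcription factors were lower for 23 of 31 members and higher for 6 (camera adjusted p = 0.000403, not passing at 0.0820 with an estimated correlation). Among them pros, a homeodomain factor, was at −3.68 ± 0.06 (1453 CPM against 18378 CPM) and Eip93F at −2.25 ± 0.03. The cAMP and memory genes were lower for 22 of 35 and higher for 10 (camera adjusted p = 0.00108, not passing at 0.209 with an estimated correlation), with Pde9 at −3.81 ± 0.06. Mitochondrially encoded genes were higher for 14 of 15 (6.21e-06, not passing at 0.195 with an estimated correlation), with mt:ND1 at 1.11 ± 0.04 and mt:CoI at 0.62 ± 0.03.

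The remaining lists, with camera adjusted p from 0.0568 to 0.789, held the following genes in α′/β′-like against α/β-like cells. Of 10 monoamine receptors 3 were higher and 7 lower (Oamb −3.86 ± 0.06, Octbeta3R −1.95 ± 0.07). Of 10 acetylcholine receptors 7 were higher (nAChRalpha7 4.12 ± 0.06, nAChRalpha6 2.16 ± 0.03) and 3 lower. Of 15 GABA, glutamate and histamine receptors 4 were higher (mGluR 2.76 ± 0.05) and 7 lower (GluClalpha −2.87 ± 0.05). Of 34 channels 13 were higher (Ca-Ma2d 2.98 ± 0.05) and 17 lower (the calcium-activated potassium channel slo −1.47 ± 0.03). Of 6 nitric oxide and cyclic GMP genes 3 were higher (the guanylyl cyclase subunit Gycbeta100B 1.60 ± 0.05) and 3 lower (Pde6 −5.41 ± 0.12). Of 19 Dpr and DIP genes 8 were higher (dpr17 4.49 ± 0.09) and 9 lower (dpr6 −1.17 ± 0.05). Of 16 Beat and Side genes 9 were higher (side-II 1.59 ± 0.05, beat-IV 1.92 ± 0.07) and 7 lower. Of 45 guidance and adhesion genes 16 were higher and 23 lower (Nrg −2.90 ± 0.05, kirre −4.27 ± 0.10). Of 30 vesicle release genes 9 were higher and 16 lower (Sytalpha as above, and the active zone scaffold Rim −2.19 ± 0.04). Of 6 neuropeptides 1 was higher and 4 lower (spab −2.58 ± 0.18). Of 7 heat shock genes 2 were higher and 3 lower (Hsromega −0.31 ± 0.03, and stv at 63.8 CPM against 129 CPM). Of 10 activity-regulated genes 3 were higher (CG46385 1.71 ± 0.05) and 6 lower (the immediate early factor sr −2.92 ± 0.15). Ribosomal protein genes went both ways, with 30 of 83 higher (RpS15Aa 0.61 ± 0.03) and 36 lower (RpL36 −0.69 ± 0.03). The innexin shakB was higher by 0.13 ± 0.03 in 7 of 8 libraries. Adjusted over the list alone, 40 in place of 39 guidance and adhesion genes and 30 in place of 29 transcription factors passed.

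γ-like cells differed from α′/β′-like cells in 3819 of 6251 genes, 1856 higher and 1963 lower, 629 of them by more than 2-fold. CAH2 (7.24 ± 0.17, 154 CPM against 0.938 CPM), the actin regulator sals (6.62 ± 0.17), bru2 (6.45 ± 0.14) and Sytalpha (5.93 ± 0.11, 602 CPM against 11.2 CPM) were higher in γ-like cells (n = 8 libraries). So were the Notch inhibitor numb (5.59 ± 0.15) and dlp (5.33 ± 0.12), together with tbc, CG13055, CG43902 and GstD11. DAT (−8.25 ± 0.09), DIP-kappa (−7.05 ± 0.16), the Musashi protein msi (−6.66 ± 0.09, 5.43 CPM against 500 CPM) and CG8641 (−6.16 ± 0.05) were lower. CG14340, CG1674, CG3655, smal, app and Lac were lower by −8.59 to −5.02. The direction was the same in 8 of 8 libraries for these 20 genes.

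In the following lists, which split γ-like from α′/β′-like cells, each camera adjusted p is followed by that with an estimated correlation, at which none passed. The cAMP and memory list had 25 of 35 genes higher and 4 lower (5.23e-08 and 0.0530). Among them were the protein kinase A regulatory subunit Pka-R2 (1.52 ± 0.03, 5870 CPM against 2046 CPM) and the scaffold kinase CASK (1.52 ± 0.03). Higher in γ-like cells were also 71 of 83 ribosomal protein genes, with RpL31 at 0.88 ± 0.03 and RpS9 at 0.94 ± 0.03, and 5 lower (2.90e-22 and 0.121). Monoamine receptors were higher for 9 of 10 genes, with Octalpha2R at 2.51 ± 0.08 and Oamb at 2.48 ± 0.07, and lower for 1 (0.00135 and 0.121). Vesicle release genes were higher for 19 of 30, with Sytalpha and Rim (1.61 ± 0.04), and lower for 5 (0.000259 and 0.143). Neuropeptide receptors were higher for 9 of 15 genes, with the sex peptide receptor SPR at 1.81 ± 0.13 and the insulin receptor InR at 0.44 ± 0.09, and lower for 3 (0.0178 and 0.121). Activity-regulated genes were higher for 6 of 10, with CG8910 at 1.98 ± 0.07 and Hr38 at 1.41 ± 0.06, and lower for 1 (0.0178 and 0.225).

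The lists with camera adjusted p from 0.0559 to 0.909 split between γ-like and α′/β′-like cells. Acetylcholine receptors were higher for 5 of 10 genes (mAChR-A 2.32 ± 0.05) and lower for 5 (nAChRalpha6 −0.77 ± 0.03). Receptors of GABA, glutamate and histamine were higher for 7 of 15 (GluClalpha 1.19 ± 0.05) and lower for 6 (Nmdar1 −1.95 ± 0.07). Of 10 transmitter genes 3 were higher and 6 lower (Ace −2.28 ± 0.04). Of 34 channels 16 were higher (slo 1.13 ± 0.03) and 14 lower (SK −1.44 ± 0.03). Of 6 nitric oxide and cyclic GMP genes 3 were higher (Pde6 2.86 ± 0.15) and 2 lower (Gycbeta100B −1.18 ± 0.04). Of 19 Dpr and DIP genes 8 were higher and 8 lower (dpr20 −2.96 ± 0.07). Of 16 Beat and Side genes 4 were higher and 8 lower (beat-VII −4.93 ± 0.09, side-II −0.80 ± 0.04). Of 45 guidance and adhesion genes 23 were higher (Nrg 2.28 ± 0.05) and 13 lower (trn −4.43 ± 0.07). Of 31 transcription factors 16 were higher (fru 2.53 ± 0.04) and 10 lower (dati −2.23 ± 0.05). Of 6 neuropeptides 3 were higher (spab 1.63 ± 0.19) and 1 lower. Of 7 heat shock genes 2 were higher (Hsp83 0.45 ± 0.05) and 4 lower (Hsromega −0.24 ± 0.03). Of 15 mitochondrial genes 7 were higher (mt:lrRNA 0.75 ± 0.03, mt:srRNA 0.50 ± 0.04) and 1 lower. The innexin shakB was higher by 0.10 ± 0.03. Adjusted over the list alone, 14 in place of 13 GABA, glutamate and histamine receptors, 17 in place of 16 Dpr and DIP genes, 77 in place of 76 ribosomal genes and 7 in place of 8 mitochondrial genes passed.

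**Figure D2:**
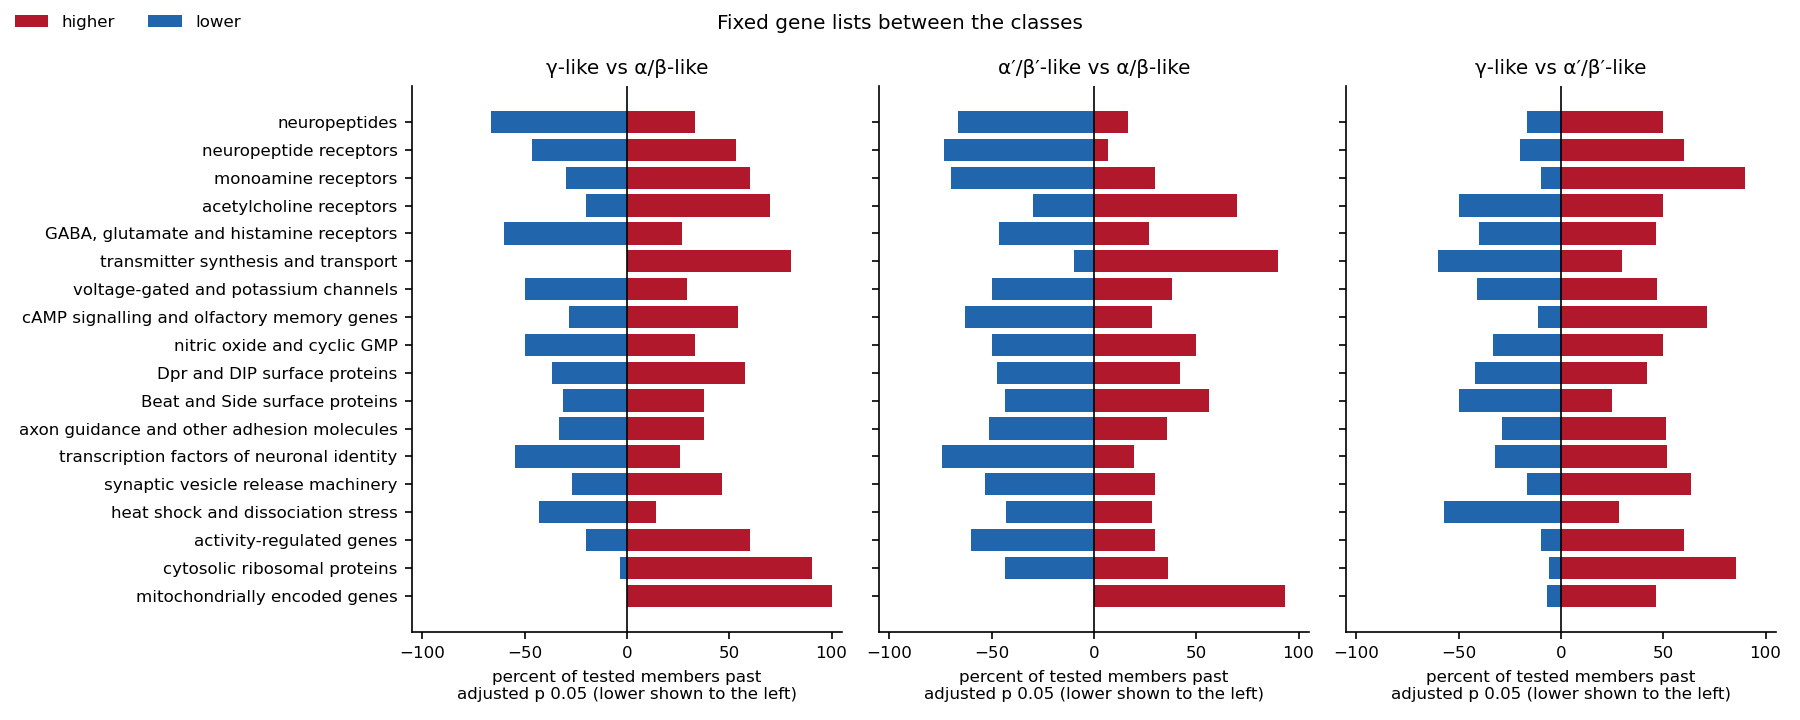
Percentage of tested members of each fixed gene list past an adjusted p of 0.05 in the 3 class contrasts, higher to the right and lower to the left. Ribosomal protein genes lay higher in γ-like cells against both other classes, where 75 of 83 and 71 of 83 members were higher.

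A reporter UMI points to a cell of a labelled subtype, so the share of positive cells was compared between driver sets. A cell with none can still belong to the subtype, so shares and fold changes can be understated. EGFP, which the sort selected for, had a UMI in 4.97% of γ-like, 7.99% of α′/β′-like and 8.28% of α/β-like cells. A cell counted as positive with at least 1 tdTomato UMI. In γ-like cells 5.42% ± 0.669 were positive in set 2 (n = 5 libraries) and 1.29% ± 0.631 in set 1 (n = 3, exact permutation p = 0.0357). In α′/β′-like cells the shares were 2.99% ± 2.65 and 15.4% ± 6.94 (exact p = 0.0357). With a threshold of 2 reporter UMIs that difference was −8.22 percentage points (exact p = 0.0714). In α/β-like cells the shares were 4.14% ± 1.10 and 8.70% ± 6.66 (exact p = 0.214). Within set 1, pool A (n = 1) had 3 of 527 γ-like cells positive (0.569%, 95% interval 0.118 to 1.65), 11 of 149 α′/β′-like cells (7.38%, 3.74 to 12.8) and 5 of 487 α/β-like cells (1.03%, 0.334 to 2.38). Pool C had means of 1.65%, 19.4% and 12.5%. Other cells, which here include glia-like cells and the 162 unnamed cells with Kenyon cell markers, were positive for 0.0870% ± 0.0555 in set 2 and 0.128% ± 0.106 in set 1. Of the 27149 other cells in neither of these groups, which overlap, 0.103% were positive. The median of all other cells was 11606 UMIs, against 7607 in γ-like, 7943 in α′/β′-like and 6033.5 in α/β-like cells. Thinned to 1000 UMIs per cell, the shares in sets 2 and 1 were 1.83% and 0.383% in γ-like, 0.752% and 5.02% in α′/β′-like, 1.68% and 3.34% in α/β-like and 0% and 0.00867% in other cells. This left out 48, 35, 32 and 902 shallower cells.

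**Figure D3:**
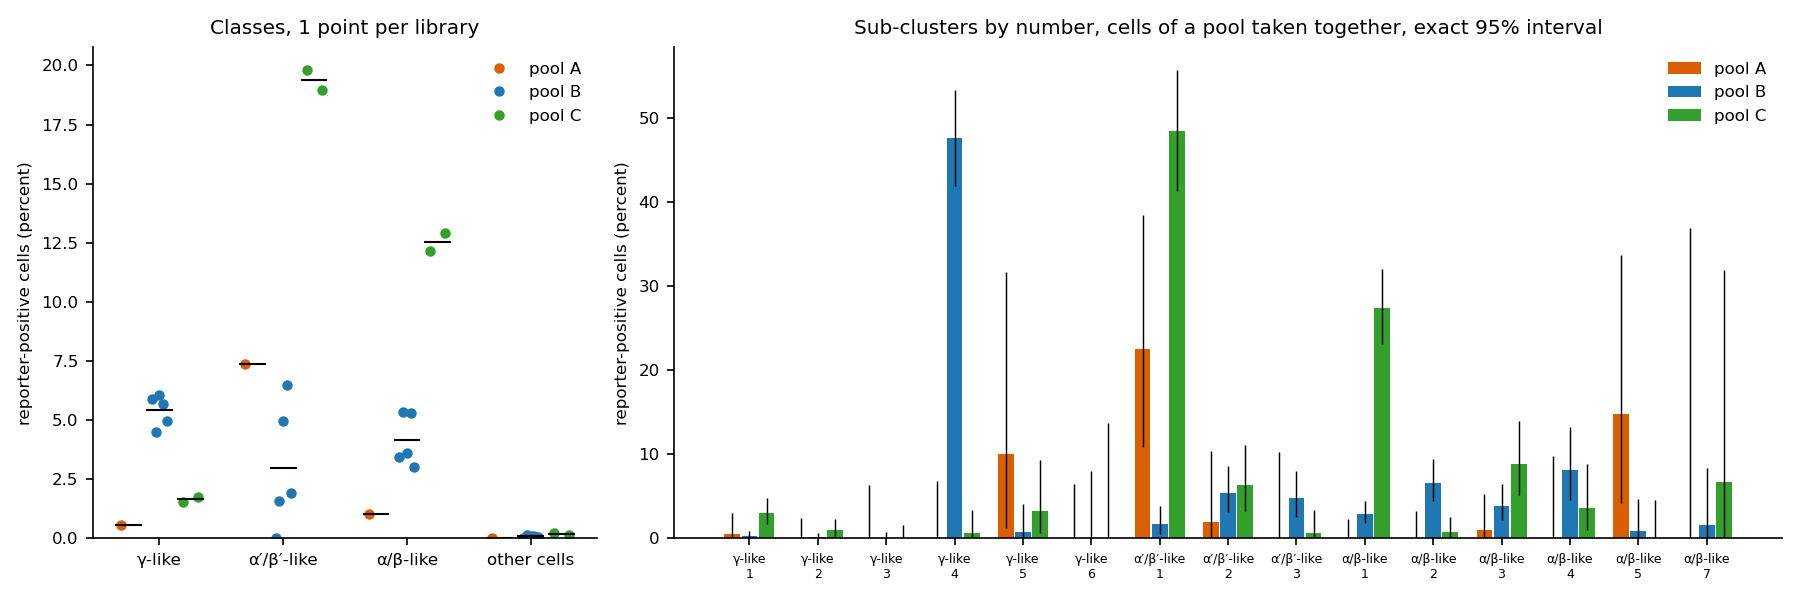
Percentage of cells with at least 1 tdTomato UMI per library, by class and pool with a line at the mean, and per sub-cluster and pool as bars with exact 95% intervals. In γ-like cells the pool B libraries had a mean of 5.42% and lay above the libraries of pools A and C, and in α′/β′-like cells they lay below them.

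Within the classes, the reporter sat in different sub-clusters of different pools. γ sub-cluster 4 (526 cells) was positive for 149 of 313 cells in pool B (47.6%), for 1 of 161 cells in pool C (0.621%) and for 0 of 52 cells in pool A (95% interval 0 to 6.85). γ sub-cluster 1 was positive for 3.00% of cells in pool C and 0.315% in pool B. α′/β′ sub-cluster 1 was positive for 96 of 198 cells in pool C (48.5%) and 9 of 40 in pool A (22.5%), against 1.68% in pool B. There α′/β′ sub-clusters 2 (5.37%) and 3 (4.78%) held most positive cells. α/β sub-cluster 1 was positive for 112 of 408 cells in pool C (27.5%) and 2.89% in pool B, where α/β sub-clusters 2 (6.62%) and 4 (8.14%) had higher shares. In pool A 4 of the 5 positive cells lay in α/β sub-cluster 5 (14.8% of 27). The lowest p of the exact permutation tests of set 2 against set 1 was 0.0357, the smallest possible. None of the 14 sub-clusters tested passed adjustment (lowest adjusted p = 0.167). A single sub-cluster at the smallest possible p cannot pass adjustment over 14 tests, so the adjusted tests cannot decide on single sub-clusters.

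The next question is which genes mark the labelled subtypes inside each class. In pool B, where the γ driver labels γd, 497 genes differed between the 156 reporter-positive γ-like cells and the rest (5 libraries). Of these, 205 were higher and 292 lower. With cells thinned to 1000 UMIs there were 176, 50 higher and 126 lower. The octopamine receptor Octbeta2R was higher by a log2 fold change of 3.61 ± 0.19 (128 ± 41.8 CPM against 10.8 ± 2.37 CPM), the phospholipase C gene norpA by 3.59 ± 0.12 (307 ± 42.7 CPM against 25.3 CPM). The transcription factor danr was higher by 3.15 ± 0.22, CG11835 by 3.01 ± 0.10 and the G-protein-coupled receptor hec by 2.77 ± 0.16. CG6154 (−4.62 ± 0.21, 16.3 CPM against 323 CPM), CAH2 (−4.26 ± 0.26), the calcium-binding protein Cbp53E (−3.03 ± 0.14), CARPB (−2.95 ± 0.23) and hoe1 (−2.42 ± 0.22) were lower. Ribosomal protein genes were lower for 17 of 82 and mitochondrially encoded genes for 6 of 13, with none higher (11 and 3 lower with DESeq2). In receptor lists, 7 of 10 acetylcholine receptor genes were lower, the octopamine and tyramine receptors Octbeta2R, Octbeta3R and Oct-TyrR were higher, and TyrR and Octalpha2R were lower. In pools A and C, whose γ driver is given for γm and γd but where γ sub-cluster 4 was positive for 1 of 161 and 0 of 52 cells, 29 positive cells in 3 libraries gave 1 gene past the threshold (194 at an unadjusted p under 0.05), the RNA of the αγ-element (2.27 ± 0.33), and edgeR gave none without replicate 8. With doublets kept there were 41 genes, 38 higher and 3 lower. Over the cells of all pools, positive γ-like cells had a median of 8252 UMIs and negative ones 7589.5. A choice by reporter UMIs can lean to deeper cells, but the mix of libraries can also give this gap. In replicate 1 the Kenyon cells had a median of 4424 UMIs and 3 of 527 γ-like cells were positive. The gap was not tested within libraries.

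In α′/β′-like cells of pools A and C, where α′/β′m is labelled, 256 genes differed between 120 reporter-positive and the other cells (3 libraries), 110 higher and 146 lower. The split was 30 and 26 with DESeq2, 25 and 24 with thinned cells and 17 and 11 without the library block. There were 80 genes without replicate 7 and 58 without replicate 8. The RNA of the αγ-element (2.82 ± 0.12), lncRNA:CR44832 (2.31 ± 0.24), CG42594 (2.05), CG4829 (1.96) and DIP-kappa (1.51 ± 0.08) were higher. CG1674 (−3.41 ± 0.25), CG6154 (−2.22 ± 0.23), the immunoglobulin protein klg, which is needed for long-term memory, Imp (−1.75 ± 0.11), which binds mRNA and sets neuronal birth-time identity, and Tektin-C were lower. Of 82 ribosomal protein genes 52 were lower and none higher (2 lower with DESeq2). Mitochondrially encoded genes moved with them, with 10 of 13 lower and none higher (2 lower with DESeq2). Over all pools the median mitochondrial share of UMIs was 1.14% in positive and 1.43% in negative α′/β′-like cells. In pool B, where α′/β′ap is labelled, 32 positive cells in replicates 4, 5 and 6 gave 20 genes, 7 higher and 13 lower (3 and 2 with DESeq2, 3 and 20 with thinned cells). There were 10 genes without replicate 4 and 9 without replicate 5. Hr38, an activity-regulated nuclear receptor, was higher by 1.36 ± 0.17, CG1265 by 1.36 ± 0.27, CG1648 by 1.26 ± 0.22 and mspo by 0.52 ± 0.13, beside the αγ-element at 2.30 ± 0.21. The rhodopsin Rh7, pros (−0.78 ± 0.11), CG31221, CG8245 and the leucine-rich repeat protein trn (−0.79) were lower. Of these genes, CG1265 and mspo fell short of the threshold without replicate 4, mspo, CG1648 and CG8245 without replicate 5, CG8245 without replicate 6, and trn without any of these replicates. With thinned cells mspo (−0.36) and trn (0.12) turned direction.

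In α/β-like cells of pool C, where α/βc is labelled, 330 genes differed between 137 reporter-positive cells and the rest in 2 libraries. Of these, 176 were higher and 154 lower (54 and 22 with DESeq2, 23 and 35 with thinned cells). Ribosomal protein genes were higher for 63 of 83 and lower for none (30 higher with DESeq2). Of 13 mitochondrially encoded genes, 6 were also higher and none lower (2 higher with DESeq2). The αγ-element (2.39 ± 0.11), the chitinase gene Cht2 (1.54), the transcription factor Hey (1.40), the sarcoglycan Scgdelta (1.27) and CG6006 were higher. CG33543 (−4.50 ± 0.41), Cbp53E (−3.37 ± 0.29), Octalpha2R, CG32683 (−2.15) and hdc were lower. In pool B, where α/βs is labelled, 79 positive cells in 5 libraries gave 52 genes, 28 higher and 24 lower. The split was 7 and 41 with thinned cells, 11 and 35 with no filter on low counts, 29 and 48 at 2 reporter UMIs, 8 and 6 without the library block and 21 and 13 with DESeq2. There were 22 genes without replicate 5 and 32 without replicate 6. The αγ-element (2.30 ± 0.14), the nesprin Msp300 (0.78 ± 0.15), the junction protein pyd (0.68), the transcription factor fru (0.51 ± 0.11) and CG42541 (0.42) were higher. The neuropeptide gene sNPF (−0.71 ± 0.08, 2667 CPM against 4349 CPM), dpr20 (−1.17), glec (−0.90), CG8245 and Scgbeta were lower. Of these, CG42541 and CG8245 fell short without replicate 4, dpr20 without replicate 3, 5 or 6, fru without replicate 6, CG8245 also without replicate 5 or 6, and Scgbeta without replicate 2, 3, 4 or 6. In pool A, where α/βp is labelled, 5 positive cells in 1 library allowed no test.

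**Figure D4:**
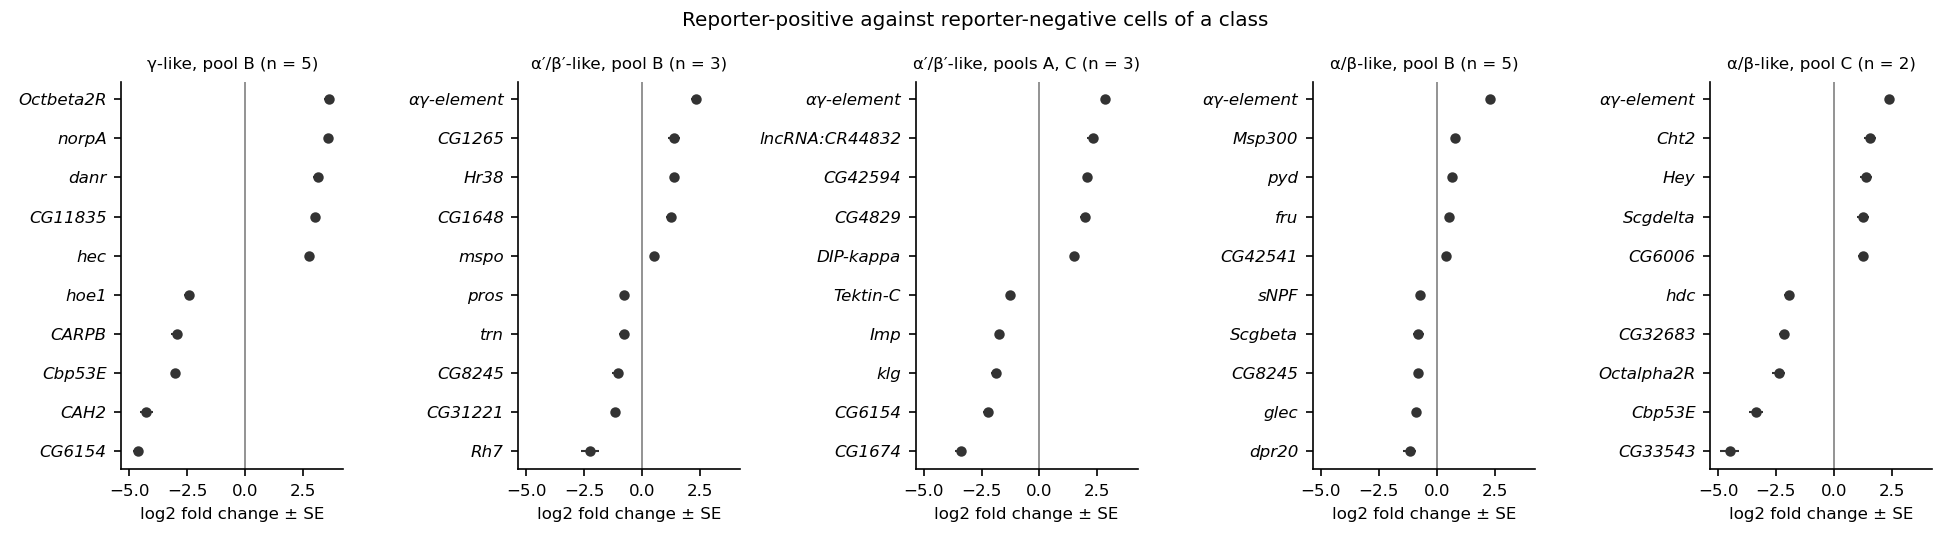
Log2 fold changes with SE of the named genes between reporter-positive and reporter-negative cells, by class and pools, with the number of libraries in each title. Octbeta2R stood at 3.61 and CG6154 at −4.62 in γ-like cells of pool B.

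The last comparison asks what differs between driver sets within a class, where the same cell classes came from pools of other genotypes. In γ-like cells 10 genes differed between set 2 and set 1, 6 higher and 4 lower. In α′/β′-like cells 6 differed, 3 in each direction, and in α/β-like cells 1 was lower. The fits did not agree on these counts. For γ-like cells DESeq2 gave 20 genes (10 higher and 10 lower), no filter on low counts 49 (24 and 25) and a term for replicates 6, 7 and 8, added after the data were seen, 26 (15 and 11). For α′/β′-like cells they gave 6 (3 and 3), 50 (11 and 39) and 12 (6 and 6), and for α/β-like cells 22 (15 and 7), 74 (29 and 45) and 29 (20 and 9). Msp300, which encodes a nesprin that links nuclei to the cytoskeleton, was lower in set 2 in every class. The log2 fold change was −1.16 ± 0.09 in γ-like cells, with 976 ± 103 CPM in pool B (n = 5), 2066 CPM in pool A (n = 1) and 2230 CPM in pool C (n = 2). It was −0.64 ± 0.10 in α′/β′-like and −1.47 ± 0.12 in α/β-like cells (226 ± 37.5, 597 and 635 CPM). In α′/β′-like cells its call was lost without replicate 2, 4, 5, 7 or 8. The other genes lay below the CPM floor of the naming rule or in the transgene, and CG9436 (5.36 CPM against 0.0548 CPM in γ-like cells) is named from them after its values were seen. Counts of genes depended on single libraries. In γ-like cells there were 159 genes without replicate 1 (43 higher and 116 lower), 4 without replicate 4 or 5 and 5 without replicate 7. For α′/β′-like cells there were 44 without replicate 1 (8 higher and 36 lower), 2 without replicate 2, 5 or 7, 1 without replicate 4 or 8 and 3 without replicate 6. For α/β-like cells the count was 147 without replicate 1 (63 higher and 84 lower) and 3 without replicate 2 or 3.

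**Figure D5:**
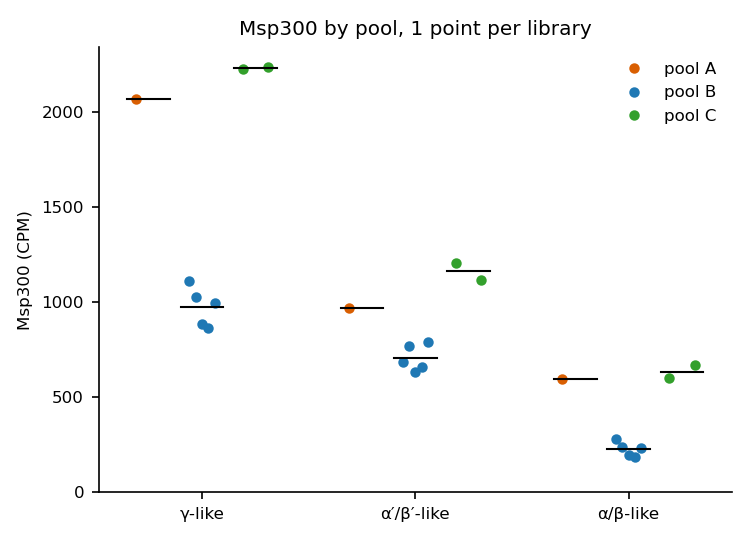
Msp300 in CPM per library, class and pool, with lines at the means. In α/β-like cells the pool B libraries had a mean of 226 CPM, against 597 CPM in pool A and 635 CPM in pool C.

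The transgenes and the dosage compensation RNAs check the labels. EGFP, which the sort selected for, was at 6.93 ± 1.34 CPM in γ-like, 11.4 ± 3.09 CPM in α′/β′-like and 14.8 ± 2.85 CPM in α/β-like cells (n = 8 libraries). tdTomato was at 14.5 ± 9.18 CPM in γ-like, 26.9 ± 26.2 CPM in α′/β′-like and 26.9 ± 21.0 CPM in α/β-like cells. roX1, a male dosage compensation RNA, was at 4.07 ± 3.19 CPM in γ-like, 19.4 ± 39.2 CPM in α′/β′-like and 45.9 ± 78.7 CPM in α/β-like cells of these female brains. roX2 was at 0.234 ± 0.181, 1.37 ± 3.11 and 10.7 ± 19.9 CPM in the same order. In α/β-like cells replicates 2 and 3, and in α′/β′-like cells replicate 3, carried most of these. roX1 was at 216 CPM in α/β-like and 114.5 CPM in α′/β′-like cells of replicate 3 and at 114 CPM in α/β-like cells of replicate 2. Without replicate 3 its mean was 3.16, 5.76 and 21.5 CPM, and without both 3.42, 6.72 and 6.19 CPM, where that of roX2 was 0.259, 0.328 and 0.164 CPM.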

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

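The tests of explanations in this part were chosen after the results were seen, while the interaction tests were planned. Reporter effects on named genes differed between driver sets, by a test of the difference itself. In γ-like cells 143 genes had a reporter effect that differed between set 2, where γd is labelled, and set 1, whose driver is given for γm and γd, with 57 shifted up and 86 down (8 libraries). CG11835 shifted by 5.195 on the log2 scale, the octopamine and tyramine receptor Oct-TyrR by 4.002, the phospholipase C gene norpA by 3.94, the pyruvate dehydrogenase kinase Pdk by 3.74 and the rhodopsin Rh7 by 3.41, and beat-VI by −5.83, CG6154 by −4.35, CAH2 by −3.81, the calcium-binding protein Cbp53E by −3.41 and CARPB by −2.94. γ sub-cluster 4 held 149 positive cells of 313 in pool B, 1 of 161 in pool C and 0 of 52 in pool A, and whether its cells are γd in set 1 was not tested. Of 56 splits of the libraries the real one gave the most genes (1 split, highest other 49). No smaller share is possible with 56 splits. Without replicate 7 there were 90 genes and without replicate 8 there were 88. There were 57 with thinned cells (25 up and 32 down) and 94 with DESeq2 (29 and 65).

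In α′/β′-like cells the reporter effect of 108 genes differed between set 2 (α′/β′ap) and set 1 (α′/β′m), 47 up and 61 down. There were 6 with cells thinned to 1000 UMIs, 28 without the library block and 48 with DESeq2. The transcription factor danr shifted by 3.97 ± 0.57 (SE), the mRNA-binding protein Imp by 2.19 ± 0.17 and CG1648 by 1.91 ± 0.27. CG34353 shifted by 1.61 ± 0.21 and the nuclear receptor Hr38 by 1.51 ± 0.23. Shifts down were −4.74 ± 0.94 for lncRNA:CR44832, −3.97 ± 0.68 for the adhesion molecule Fas2 and −3.54 ± 0.36 for Rh7. The growth factor ligand Pvf3 shifted by −2.57 ± 0.36 and the phosphodiesterase Pde9 by −2.47 ± 0.43. The count was 53 without replicate 5, 63 without replicate 7 and 61 without replicate 8, and the 10 possible splits are too few for a share under 0.05 (1 split, highest other 15). In α/β-like cells 159 genes differed between set 2 (α/βs) and pool C (α/βc), 86 up and 73 down (14 and 48 with thinned cells, 81 and 112 at 2 reporter UMIs, 50 and 70 with no filter on low counts, 36 and 23 without the library block, 43 and 30 with DESeq2), with 49 without replicate 7 and 51 without replicate 8. Cbp53E shifted by 2.67 ± 0.49 (SE), the junction protein pyd by 1.26 ± 0.15 and CG42541 by 1.16 ± 0.13. The shift was 1.12 ± 0.35 for bc10 and 1.10 ± 0.34 for the histone methyltransferase Hmt4-20. Shifts down were −2.17 ± 0.37 for CG6006, −1.83 ± 0.32 for the surface protein dpr20 and −1.71 ± 0.46 for the proteasome subunit Rpn6. CG31997 shifted by −1.52 ± 0.22 and Pvf3 by −1.44 ± 0.22. Leaving out a single library ended the calls of lncRNA:CR44832 (replicate 5), Rpn6 (replicate 7 or 8), bc10 (replicate 4, 5, 7 or 8) and Hmt4-20 (any of replicates 2 to 8).

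Values of 1 library stood apart from the rest of its pool in 2 of 15 cases tested, where chance gives about 1 in 20. The α′/β′-like share was 6.05% of analysed cells in replicate 2, against 4.01% to 4.34% in the other libraries of pool B. Replicate 2 also had the highest Kenyon cell share (34.1%). As a share of Kenyon cells the α′/β′-like cells were 17.8% in replicate 2, against 14.0% to 16.7% in the others. That share was not tested for a library that stands apart. The share of Kenyon cells with a UMI of roX1, an RNA of male dosage compensation, was 2.87% in replicate 3, against 0.789% to 1.35% in the others.

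The RNA of the αγ-element, a noncoding gene of the Hsp70 locus whose sequence is shared with heat shock gene copies, was higher in reporter-positive cells of all 6 reporter contrasts, by log2 fold changes from 2.27 to 2.82. Expression by all cells of a labelled sub-cluster alike is argued against, since the ratio of reporter-positive to reporter-negative cells within it was at least 2.55 in each library of pool B for γ sub-cluster 4, at least 3.96 in those of pools A and C for α′/β′ sub-cluster 1, and at least 4.11 in those of pool C for α/β sub-cluster 1. A subtype finer than these sub-clusters stays open. Reporter-negative cells gave no common answer between sets. In γ sub-cluster 4 set 2 held 82.5 ± 8.94 CPM (n = 4) and set 1 29.6 ± 12.5 CPM (n = 3, exact permutation p = 0.0571, the smallest possible). Set 2 lay at 69.7 CPM or more and set 1 at 43.1 CPM or less. Replicate 2, whose 9 negative cells held 192 CPM, was left out there. However, α′/β′ sub-cluster 1 held 83.04 in set 2 and 73.4 CPM in set 1 (exact p = 0.643). In α/β-like cells outside sub-cluster 1, set 2 was also higher, by a ratio of 1.55 (exact p = 0.0357). Hsp70Bb, a gene of the same locus, was also higher in 3 of the 6 contrasts and was left out of the next test. A heat shock gene other than Hsp70Bb was higher in 1 of the 6 contrasts. That count cannot decide on a heat shock response, since Hsp70Bb was left out and some contrasts could find little. Of simulated 2-fold changes, γ-like cells of pools A and C recovered 16.4% and α′/β′-like cells of pool B 19.7%. Against the direction of such a response, Hsromega was lower in γ-like cells of pool B (−0.78 ± 0.05) and Hsp83 in α/β-like cells of pool C (−0.57 ± 0.09). A heat shock response stays open. Reads of the reporter transgene counted on the element stay open and untested, since its sequence was not used here, as does an effect of each driver line.

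The γ-like reporter share was lower in set 1, whose driver is given for more γ subtypes, than in set 2. Depth is argued against, since shares thinned to 1000 UMIs still gave a ratio of 4.77 between set 2 and set 1. Free reporter RNA as the source of the positive γ-like cells in set 1 is argued against, since their share was 10.1 times that of other cells in set 1. A weaker driver line and other differences between the genotypes may explain it, stay open and were not tested.

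A signal outside the comparisons was found in roX1, of which 22 cells held 20 or more UMIs, 20 of them Kenyon cells and 17 of them in replicates 2 and 3. Free RNA is argued against, since 81.8% of these cells also held a roX2 UMI, against 0.583% of the other cells. A male brain in the pool is argued against by the 17 of 1351 Kenyon cells but 0 of 2881 other cells of replicates 2 and 3 that were rich in roX1 (Fisher's exact p = 3.47e-09, with up to 0.104% allowed in the other cells and 36.3 cells to be found at the Kenyon cell share). Of the 17 cells, 16 were among 706 α/β-like and α′/β′-like cells and 1 among 645 γ-like cells (Fisher's exact p = 0.000311). Both Fisher tests count cells, so their p-values do not measure the spread between libraries. Replicates 2 and 3 were picked after the signal was seen. Rich in roX1 were 4 of 445 Kenyon cells and 0 of 861 other cells in replicate 2. In replicate 3 they were 13 of 906 and 0 of 2020. The cause stays open, and no biological explanation within female brains was tested.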

How the results depend on the processing

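Within this part, the alternatives with a term for replicates 6, 7 and 8, with at least 5 positive cells per sum and with stricter doublet removal were chosen after the data were seen. Of 2808 values of named genes in class contrasts 2803 kept their call and 5 fell short of the threshold, of 926 in reporter contrasts 829 kept it, 95 fell short and 2 reversed, of 217 between driver sets 161 kept it and 56 fell short, and of 918 list values 880 kept it, 32 newly passed, 5 fell short and 1 reversed. The reversed values are mspo (−0.364) and trn (0.117) in α′/β′-like cells of pool B with thinned cells, and the direction that camera gave the Beat and Side list between γ-like and α/β-like cells with doublets kept (median 1.83, adjusted p = 0.00808, against a median of 0.02 and adjusted p = 0.933). Where no cause is named, the cause was not tested.

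With sums thinned to the smallest, 2106 genes differed between γ-like and α/β-like and 2458 between γ-like and α′/β′-like cells, since fewer counts were left. With cells thinned to 1000 UMIs, which leaves fewer positive cells, the reporter contrasts gave 176 (γ, pool B, 50 higher and 126 lower), 0 (γ, pools A and C, with 1 gene unthinned by edgeR and 1 by DESeq2), 49 (α′/β′, pools A and C) and 58 (α/β, pool C) genes and the interactions 57 (γ), 6 (α′/β′) and 62 (α/β).

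With DESeq2 the reporter contrasts gave 5 genes (α′/β′, pool B, 3 higher and 2 lower), 56 (α′/β′, pools A and C, 30 higher and 26 lower against 110 and 146), 34 (α/β, pool B) and 76 (α/β, pool C, 54 higher and 22 lower against 176 and 154), the interactions 94 (γ), 48 (α′/β′) and 73 (α/β), and the driver sets 20 (γ) and 22 (α/β, 15 higher and 7 lower). Without the library block there were 28 (α′/β′, pools A and C), 14 (α/β, pool B), and for interactions 77 (γ), 28 (α′/β′) and 59 (α/β). With a threshold of 2 reporter UMIs there were 2 (γ, pools A and C) and 143 (α′/β′, pools A and C), and the difference in α′/β′-like reporter share was −8.22 percentage points (exact permutation p = 0.0714). With doublets kept, γ in pools A and C gave 41.

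Between driver sets, no filter on low counts gave 49 (γ), 50 (α′/β′) and 74 (α/β) genes, pool B against pool C alone 159, 44 and 147, and a term for replicates 6, 7 and 8 gave 26, 12 and 29.

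Leaving out 1 library at a time gave 368 to 486 genes for γ in pool B, 0 to 1 for γ in pools A and C (0 without replicate 8), 9 to 22 for α′/β′ in pool B (10 without replicate 4, 9 without replicate 5), 58 to 324 for α′/β′ in pools A and C (80 without replicate 7, 58 without replicate 8) and 22 to 53 for α/β in pool B. The interactions gave 88 to 149 (γ), 53 to 113 (α′/β′) and 49 to 163 (α/β), and the driver sets 4 to 159 (γ), 1 to 44 (α′/β′) and 1 to 147 (α/β), where replicate 1 gave the highest count. α/β in pool C has 2 libraries and allows no such test. Set 2 minus set 1 ranged from −0.381 to 3.03 (γ), −0.604 to 0.843 (α′/β′) and −0.551 to 0.740 (α/β) for class shares, reversed in γ-like cells without replicate 1 (−0.381), in α′/β′-like cells without replicate 1 (−0.604) and 2 (−0.0218) and in α/β-like cells without replicates 1 (−0.551), 2 (−0.119) and 3 (−0.376). For reporter shares it ranged from 3.77 to 4.37 (γ), −16.4 to −10.2 (α′/β′) and −8.40 to −2.46 (α/β), where fewer libraries leave a smallest exact p of 0.0571 or 0.0952.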

Other observations

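The splits of libraries into other groups, the limits used to read them and the search for a structure behind them were chosen after the results were seen. For γ-like against α/β-like cells the real grouping gave 3591 genes and the highest of the other splits 2499, for α′/β′-like against α/β-like cells 3855 and 26, and for γ-like against α′/β′-like cells 3819 and 2768. In each case 1 of the 24 splits run, of 128 possible, gave as many genes, and it was the real one. The classes came from clustering the same cells by expression, so an exchange of their labels was bound to give fewer genes. These splits therefore cannot decide on chance.

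For the reporter contrasts the splits were too few for a share under 0.05. The γ contrast gave 497 genes in pool B, with a highest other count of 6 among 16 splits, and 1 gene in pools A and C, where 3 of 4 splits gave as many and the highest other count was 5. The α′/β′ contrast gave 20 genes in pool B (highest other 5 of 4 splits) and 256 in pools A and C (highest other 12), and the α/β contrast gave 52 in pool B (highest other 16).

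Between driver sets, as many genes as the real 10, 6 and 1 were found in 3 of 56 splits in γ-like, 4 of 56 in α′/β′-like and 11 of 56 in α/β-like cells, so chance is not excluded for these counts. The highest counts, 219 genes in γ-like, 259 in α′/β′-like and 213 in α/β-like cells, came from setting replicates 6, 7 and 8 against the rest, which points to a structure of the samples other than the driver sets. The first principal component of the libraries, with 56.3%, 45.5% and 50.9% of the variance in the same order, also put replicate 1 at one end and replicates 6, 7 and 8 at the other. Ribosomal protein genes took 8.14%, 8.08% and 8.38% of Kenyon cell UMIs in replicates 6, 7 and 8 and 6.77% to 7.47% in the others. With a term for replicates 6, 7 and 8, chosen after the data were seen, 26, 12 and 29 genes differed between the sets.

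In α′/β′-like cells CG13324, CG9436 and CG13323 were at 11.0 ± 3.59, 5.64 ± 1.52 and 6.79 ± 3.01 CPM in set 2 (n = 5 libraries) and had no UMI in set 1 (n = 3), which allows up to 0.524 CPM over the group. These genes and lncRNA:CR44832 (14.7 CPM in set 2, 43.5 CPM in set 1) were chosen after their values were seen. Of 10021 Kenyon cells, 9689 (96.7%) fell in the same class when clustered on either set of genes. In the 5 reporter-positive α/β-like cells of pool A, CG11835 was at 441 CPM and Cbp53E at 588 CPM, against 25.9 CPM and 112 CPM in the 482 negative cells, in 1 library with no test. These values rest on 9 and 12 UMIs, and no fixed rule chose the genes. Other genes were lower in the positive cells, such as norpA (49.0 against 456 CPM) and glec (245 against 1156 CPM).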
